A study of Danio rerio with 6 samples.

How the data were processed

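Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, and binding of the transcription factor sox10. The series holds 6 libraries from zebrafish: 3 ChIP libraries and 3 input libraries, with 1 library per group. The ChIP libraries are H3K27ac in the melanoma cell line zcrest, sox10 in the same line, and H3K27ac in a freshly dissected primary melanoma. Peak lists of the 3 ChIP libraries were analysed, and the input libraries were not used here as separate data.

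Per the submitters' processing notes, reads were aligned with Bowtie to the Zv9 assembly and peaks were called with MACS2 version 2.0. The Bowtie version, the control used for calling and the calling thresholds are not given in the sources used here. The peak names in the deposited lists begin with MACS2. Per the labels, each deposited list belongs to 1 library, and pooling is not described. The deposited lists give, per peak, a position, a summit, a fold enrichment (a ratio over the caller's own background) and the −log10 of the p-value and of the q-value. The deposited score was the −log10 q multiplied by 10 and truncated to a whole number in every peak of the 3 lists. The highest q in the lists was 0.0497, so the lists end at a q of about 0.05. No peaks of a list overlapped each other. Fold enrichments and q-values are the authors' values for each peak. In the values reported here they were used only to describe, rank, score or filter peaks within their own list. Comparisons of them between lists were run but dropped. Read depth is unknown from these files, and the number of peaks a caller returns depends on it. Differences in peak number between lists therefore have no replicate check and no depth correction.

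Analyses were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Positions are 1-based on Zv9. Chromosome ends were taken as the last peak end over the 3 lists, for a total span of 1356 Mb. Peaks were counted as overlapping when they shared at least 1 base. Each overlap was compared with 1000 shuffles in which the peaks of the first list were moved at random along their own chromosome with their widths kept. An observed number outside the central 95% of the shuffles was called above or below the shuffled level. These shuffles describe where the peaks of 2 libraries lie, and they are not a test between conditions. Assembly gaps and unmappable sequence were not modelled. For the H3K27ac lists, peaks within 12500 bases were stitched into domains. Each domain was scored by the sum of peak width multiplied by fold enrichment, and domains above the point where the scaled rank curve has a slope of 1 are called superenhancer-like. This score uses peak lists in place of read densities and approximates the usual procedure. For sox10 inside domains, the sox10 peaks lying on H3K27ac peaks were redistributed 1000 times within their chromosome, in proportion to H3K27ac peak bases. This treats sox10 peaks as independent, and its range is too narrow for clustered peaks. Shares of peaks carry exact (Clopper-Pearson) 95% intervals that cover counting error only, and neighbouring peaks are not independent.

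The shuffle was tested on simulated data with 4196 sox10 peaks against the cell line H3K27ac list. In scattered lists, 5% or 30% of the peaks were planted on H3K27ac peaks, and 5.15% and 29.7% were recovered. Recovery was not tried on lists with the real clustering of the sox10 peaks. In lists with no effect, moving each peak alone called 5% of 100 scattered lists. It called 44% of 100 lists that kept the real spacing of the sox10 peaks within clusters. Moving clusters together called 8% of the latter. Because of the 44%, a shuffle that moves sox10 peaks closer than 5 kb together was added after the data had been seen. So were the separate values for blocks of at least 5 such peaks. The clustered lists were made by moving the same clusters, so the low rate of 8% was built in. Real clusters also lie near each other, as on chromosome 16 from 20231787 to 20278222 and from 20284451 to 20326488. The range of the cluster shuffle may therefore still be too narrow.

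The overlaps, the domains, the sox10 shares by H3K27ac decile, the processing alternatives listed here and the rule for naming regions were fixed before the data were examined. Added afterwards were all settings with clusters, blocks and isolated sox10 peaks, the spacing of peaks, their numbers per window and per chromosome, the other shares by decile and all tests of technical explanations. Regions are named as the 10 sox10 peaks with the highest fold enrichment, the 10 highest domains of each H3K27ac list, the 10 with the smallest sum of ranks in both, the 5 domains with the most sox10 peaks, and the 5 highest domains of each list without a peak of the other. Alternatives covered stricter q-values, other overlap rules, a local shuffle, equal list lengths, other stitching distances and other domain scores. The alternatives for the overlap of the H3K27ac lists used 200 shuffles each. Analyses that need an annotation or the sequence of Zv9 were planned but not run: location relative to promoters, lists of neural crest, pigment cell and other marker genes, and the sox10 motif. Gene tables on GRCz12tu coordinates were not used to name peaks, because positions differ between assemblies. Regions are therefore given by coordinates without gene names.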

Results

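H3K27ac and sox10 binding were mapped in zcrest, a passaged zebrafish melanoma line, and H3K27ac was mapped in a primary melanoma. The labels give the founder genotype of both sources as p53/BRAF/Na, with MiniCoopR, a vector that carries a mitfa minigene. The founder of the line also carried crestin:EGFP, a reporter of the neural crest, and the tumor arose after injection of a control vector with mitf:EGFP. Sox10 is a transcription factor of the neural crest and of the melanocyte lineage. The cell line H3K27ac list held 50338 peaks over 19.8 Mb, the tumor H3K27ac list 59760 peaks over 18.0 Mb, and the sox10 list 4202 peaks over 0.514 Mb. Median peak widths were 296, 239 and 85 bases, and median fold enrichments were 5.31, 5.56 and 4.88, in the same order. There were no replicates, so the values below describe single libraries, and read depth is unknown.

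The first comparison asked how far the active regions of the cell line and of the tumor coincide. Of the cell line H3K27ac peaks, 24099 (47.9%) overlapped a tumor peak, 16.3 times the shuffled mean of 1477 ± 38.4 (SD over 1000 shuffles). Of the tumor peaks, 23808 (39.8%) overlapped a cell line peak, 16.4 times the shuffled mean. No shuffle reached either number. The lists shared 6.69 Mb, a Jaccard index of 0.215.

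The strongest peaks of each source were the ones most often found in the other. In the tumor list, the share found in the cell line rose in every decile of fold enrichment, from 15.5% in the lowest to 82.0% in the highest. In the cell line list it was 46.4% in the lowest decile, 35.3% in the third and 69.0% in the highest. Cell line peaks found in the tumor had a median width of 403 bases and a median fold enrichment of 5.96, against 232 bases and 4.89 for the others. Tumor peaks found in the cell line had a median width of 311 bases and a median fold of 6.96, against 208 bases and 4.91.

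**Figure D1:**
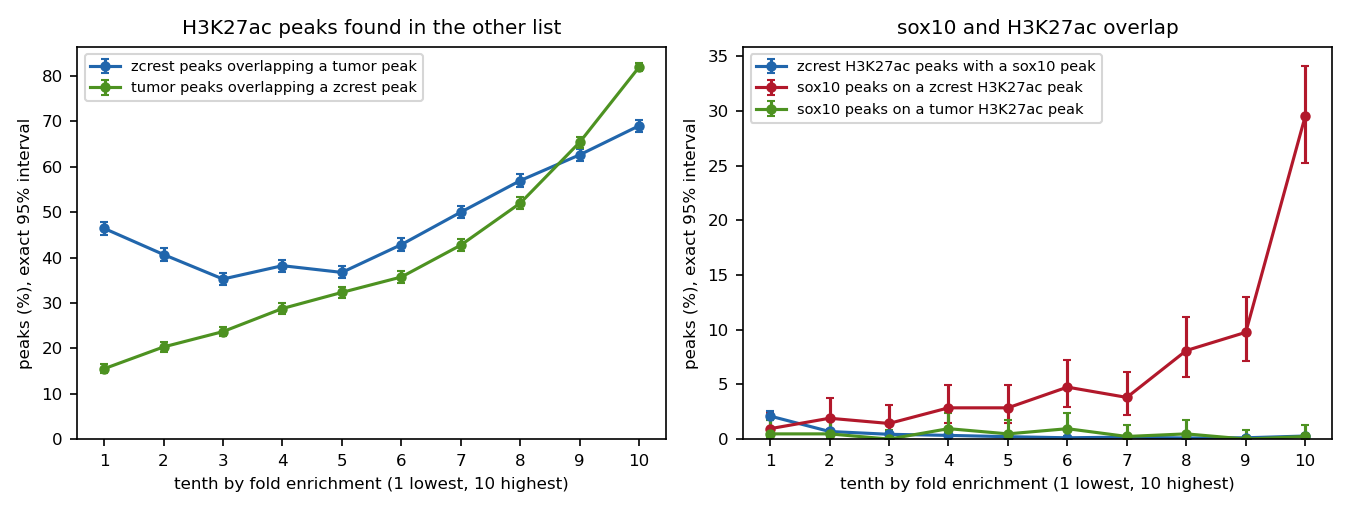
Share of peaks (%, y axis, with exact 95% intervals for counting error) against the decile of fold enrichment (x axis, 1 lowest to 10 highest), for H3K27ac peaks found in the other H3K27ac list (left) and for sox10 against H3K27ac (right). Tumor peaks climb from 15.5% to 82.0%, and sox10 peaks on cell line H3K27ac reach 29.5% in the highest decile while those on tumor H3K27ac stay near 0.

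Large acetylated domains were also shared beyond the shuffled level. Stitching gave 16353 domains in the cell line, 601 of them superenhancer-like, and 18985 in the tumor, 803 of them superenhancer-like. These held 21.4% and 27.3% of all peaks. Of the 601 cell line domains, 337 (56.1%) overlapped a superenhancer-like domain of the tumor, against a shuffled mean of 32.3 ± 5.55 (SD). From the tumor side the number was 323 of 803 (40.2%), against 32.2 ± 5.39. Only 6 of the 601 and 6 of the 803 contained no H3K27ac peak of the other source at all. The cell line domains were shorter and more densely filled: the median length was 27.9 kb with 25.9% of bases inside peaks, against 47.6 kb and 12.3% in the tumor.

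**Figure D2:**
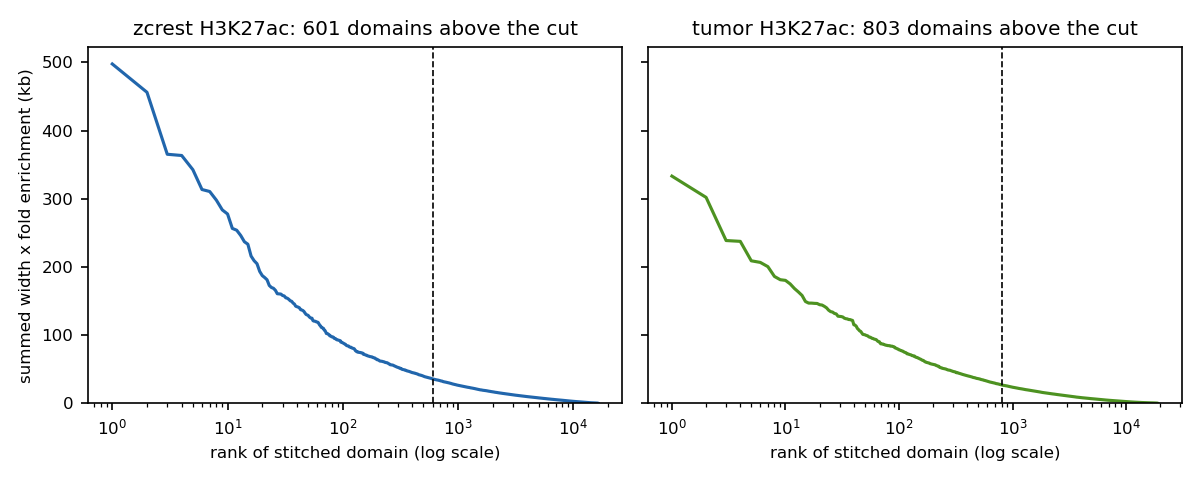
Summed width × fold enrichment of each stitched H3K27ac domain (y axis, kb) against its rank (x axis, log scale) in the cell line (left) and the tumor (right). The dashed lines mark the cut, with 601 domains above it in the cell line and 803 in the tumor.

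By the sum of the ranks in the 2 lists, the first 3 domains lay on chromosomes 9, 6 and 17. The first spanned chromosome 9 from 9082614 to 9223433 (rank 4 in the cell line, rank 7 in the tumor, 80 cell line peaks over 141 kb). The second spanned chromosome 6 from 30534167 to 30613244 (ranks 3 and 16) and the third chromosome 17 from 27875819 to 28013432 (ranks 2 and 20). The other 7 were on chromosome 5 from 34153570 to 34232048 (ranks 21 and 3), chromosome 9 from 26710243 to 26764099 (17 and 8), chromosome 19 from 28959448 to 29045207 (18 and 11), chromosome 12 from 36944219 to 37065618 (16 and 15), chromosome 4 from 16246977 to 16301579 (30 and 2), chromosome 23 from 36101183 to 36143069 (8 and 26) and chromosome 2 from 47574952 to 47628272 (7 and 37).

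**Figure D3:**
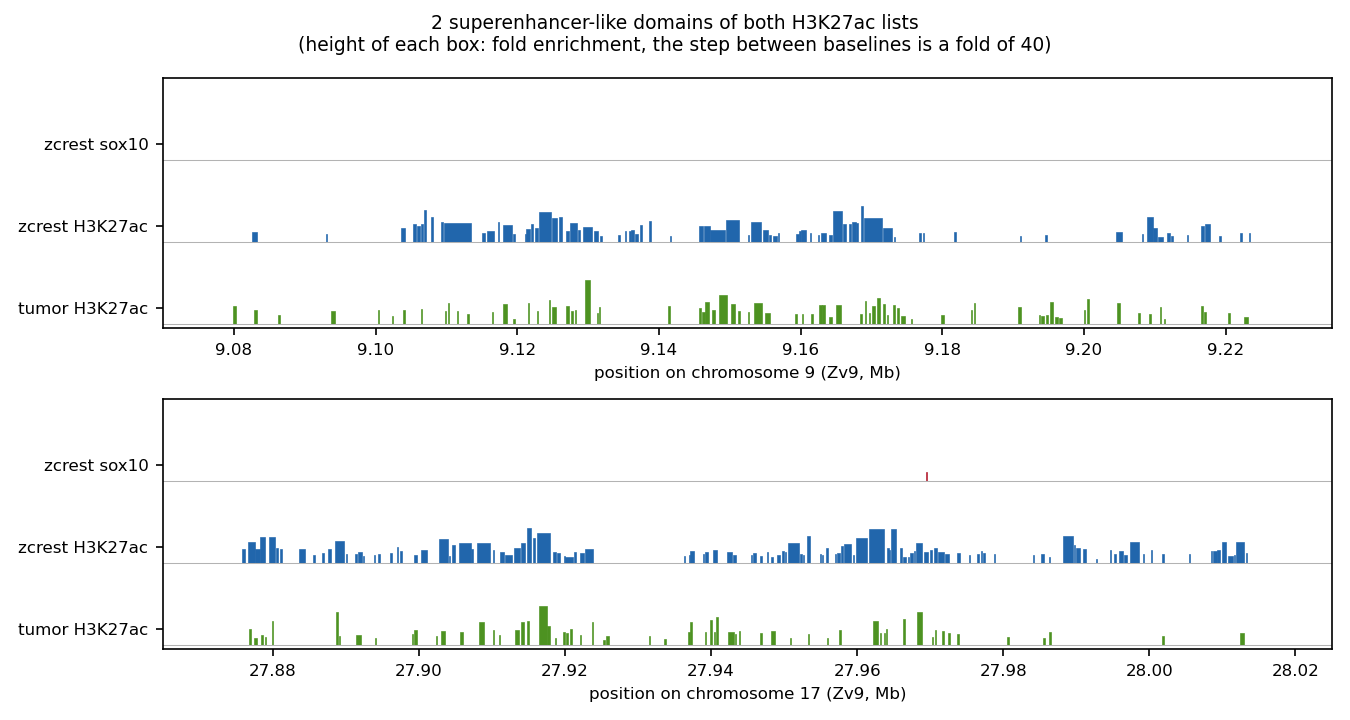
Peaks of the 3 lists (boxes, with height showing fold enrichment) along chromosome 9 and chromosome 17 (x axis, Zv9 position in Mb) at 2 domains ranked high in both H3K27ac lists. Cell line peaks number 80 and 119 and tumor peaks 75 and 63, while sox10 has 0 and 1.

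Other leading domains differed in rank. The highest domain of the cell line, on chromosome 9 from 14776980 to 14989207, held 157 peaks and ranked 52 in the tumor. A domain on chromosome 6 from 43312484 to 43365263 ranked 5 in the cell line, where peaks filled 63.1% of it, and 166 in the tumor. Domains on chromosome 25 from 18778011 to 18922739, chromosome 19 from 22932980 to 23029714 and chromosome 21 from 18933494 to 19055164 ranked 6, 9 and 10 in the cell line and 51, 452 and 528 in the tumor. In the tumor, the highest domain was on chromosome 22 from 18768747 to 19027880 (121 peaks) and ranked 204 in the cell line. Tumor ranks 2 and 3 were the chromosome 4 and chromosome 5 domains above in longer form. Ranks 4, 5 and 6 were on chromosome 23 from 22974578 to 23210501, chromosome 3 from 55458244 to 55613476 and chromosome 23 from 35857400 to 36079772, with cell line ranks of 266, 88 and 84. Ranks 9 and 10 were on chromosome 10 from 28874950 to 28981882 and chromosome 4 from 10560917 to 10790956, with cell line ranks of 200 and 161. The ranks come from lists of different length and show position within a list, not a change in acetylation.

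Superenhancer-like domains without a peak of the other source were of lower rank. In the cell line the highest 5 lay on chromosome 7 from 71827066 to 71885416 (rank 158), chromosome 11 from 15456748 to 15484879 (356), chromosome 22 from 30453066 to 30471383 (440), chromosome 18 from 11718712 to 11720033 (489) and chromosome 9 from 34837125 to 34840143 (490). The chromosome 18 domain was a single peak of 1322 bases with a fold enrichment of 30.7, the highest value in its list. In the tumor the highest 5 lay on chromosome 5 from 45550918 to 45564242 (429), chromosome 11 from 23125762 to 23179247 (516), chromosome 1 from 53034633 to 53068323 (530), chromosome 5 from 9564040 to 9593164 (727) and chromosome 3 from 56530381 to 56546926 (792).

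Sox10 peaks in the cell line were packed into few places. The 10 fullest windows of 1 Mb, out of 1370, held 2017 sox10 peaks (48.0%), against 3.16% of cell line and 2.89% of tumor H3K27ac peaks in their own 10 fullest windows. The median gap between neighbouring sox10 peaks was 237 bases, against 2055 and 4468 bases in the cell line and tumor H3K27ac lists. Blocks of at least 5 peaks separated by less than 5 kb numbered 122, covered 1.47 Mb and held 3473 peaks (82.7%). Of these, 16 blocks of 50 or more peaks held 2000 peaks. The fullest was on chromosome 14 from 47119920 to 47200229, with 219 peaks in 80.3 kb. The next were on chromosome 24 from 12371357 to 12446730 (218 peaks) and chromosome 12 from 15431074 to 15480844 (210 peaks). Outside the blocks lay 729 peaks, 455 of them isolated.

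The sox10 peaks with the highest fold enrichment, from 19.4 to 32.9, came from 7 clusters. They lay on chromosome 7 from 72152204 to 72152423 (32.9-fold), chromosome 13 from 4322037 to 4322886 (31.2), chromosome 8 from 32015983 to 32016212 (25.2) and from 32014553 to 32014624 (24.1), chromosome 24 from 3326782 to 3327396 (21.9) and from 3332108 to 3332283 (21.4), chromosome 18 from 42241588 to 42242171 (20.8) and from 42243204 to 42243418 (20.6), chromosome 16 from 9256529 to 9256712 (20.6) and chromosome 22 from 25159424 to 25159570 (19.4). Of these 10 peaks, 8 overlapped H3K27ac of the cell line and 0 overlapped H3K27ac of the tumor, and 8 lay in blocks.

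The series also asked how sox10 binding relates to H3K27ac in the cell line. Of the sox10 peaks, 277 (6.59%, interval 5.86% to 7.38%) overlapped an H3K27ac peak of the cell line, 3.51 times the shuffled mean of 78.9 ± 8.96 (SD). With clusters moved together the shuffled spread was larger (78.0 ± 21.1), and no shuffle reached 277. That spread may still be too small, since neighbouring clusters were moved independently of each other. The overlap grew with sox10 fold enrichment, from 0.95% in the lowest decile to 29.5% in the highest. It was 0.60% in the 16 blocks of 50 or more peaks. All 12 overlapping peaks of these blocks lay in 1 block on chromosome 14 from 29795824 to 29827400. The share was 6.94% in blocks of 20 to 49 peaks and 15.9% in blocks of 5 to 19 peaks. Outside blocks 102 of 729 peaks overlapped, 7.66 times the shuffled mean. When both lists were limited to a −log10 q of 5 or more, 127 of 3231 sox10 peaks (3.93%) overlapped, above the shuffled range, and at 10 or more 30 of 1759 (1.71%), inside it. These shuffles moved each peak alone, so their ranges are too narrow for clustered peaks. The cut at 10 kept 47.0% of sox10 peaks in blocks and 17.6% of the others.

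The acetylated regions under sox10 had low fold enrichments. The 231 cell line H3K27ac peaks with a sox10 peak had a median fold enrichment of 3.42, against 5.33 for the others. The median was 2.94 for the 141 under sox10 blocks and 4.50 for the 90 under other sox10 peaks. A sox10 peak was present on 2.11% of H3K27ac peaks in the lowest decile of fold enrichment and on 0.28% in the highest. Without sox10 blocks the share in the lowest decile was 0.46% (23 of 5034), and that in the highest was again 0.28% (14 of 5033). Ranked by width, the share was 0.50% in the lowest decile and 0.48% in the highest.

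Sox10 sites of the cell line seldom lay in acetylated regions of the tumor. Only 18 of the 4202 sox10 peaks (0.43%, interval 0.25% to 0.68%) overlapped a tumor H3K27ac peak, 0.24 times the shuffled mean of 75.6 ± 8.47 (SD). No shuffle was as low, with peaks moved alone or clusters moved together (75.4 ± 18.9). Here too neighbouring clusters were moved independently, so the latter spread may be too small. Outside blocks the number was 10 of 729 (1.37%), inside the shuffled range around 12.5. At a −log10 q of 5 or more it was 2 of 3231 (0.06%), below the range with each peak moved alone. That cut favours peaks in blocks, whose median −log10 q was 9.48 against 4.63 outside, so it is no check apart from the blocks. The 141 cell line H3K27ac peaks under sox10 blocks included 0 found in the tumor list. Of the 90 under other sox10 peaks, 16 (17.8%) were found in the tumor, against 48.1% of cell line H3K27ac peaks without sox10.

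**Figure D4:**
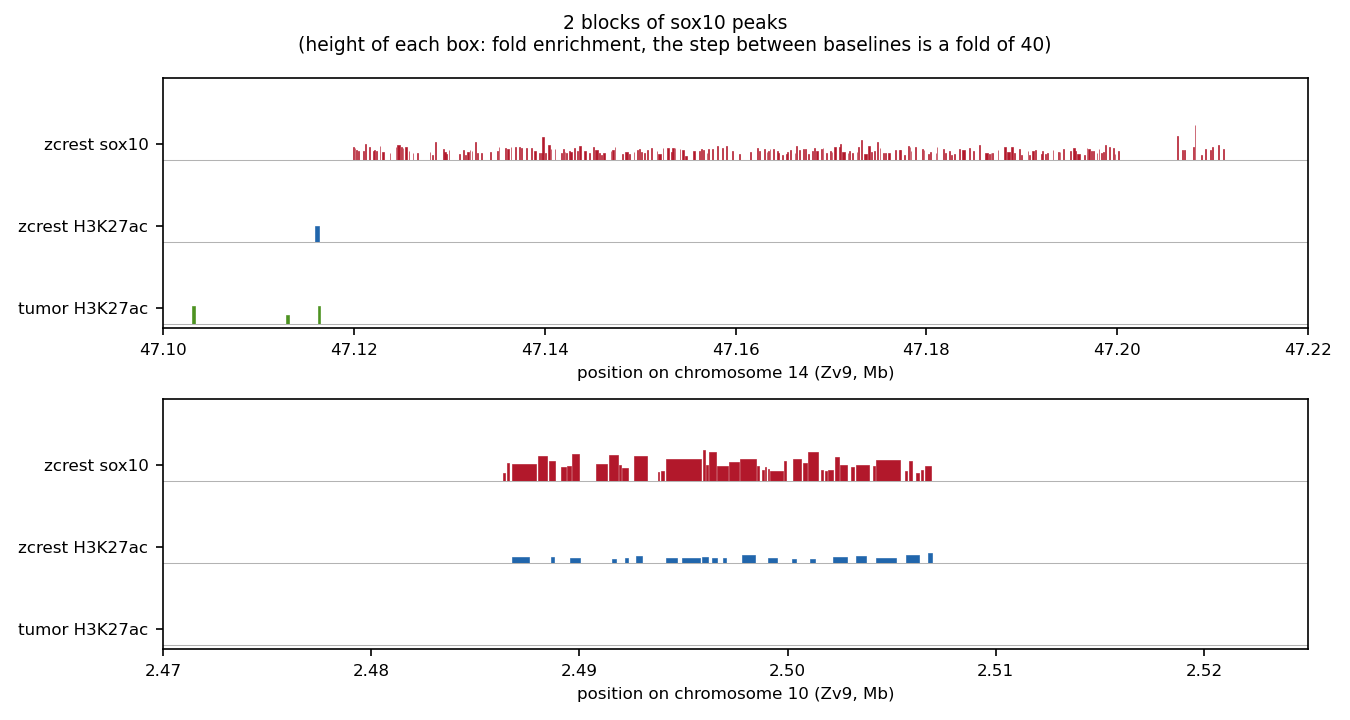
Peaks of the 3 lists (boxes, with height showing fold enrichment) along chromosome 14 and chromosome 10 (x axis, Zv9 position in Mb) at 2 blocks of sox10 peaks. The chromosome 14 block has no H3K27ac peak inside it, and the chromosome 10 block has 45 sox10 and 20 cell line H3K27ac peaks and none of the tumor.

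Superenhancer-like domains of the cell line held few sox10 peaks. Of the 601 domains, 19 contained any, with 34 sox10 peaks in all. On H3K27ac peaks, sox10 peaks numbered 27 inside these domains, in 18 clusters, and 250 in the others, in 110 clusters. Per base of H3K27ac peak the ratio was 0.31. Redistribution gave 70.9 ± 7.12 (SD) inside. Without sox10 blocks the numbers were 21 and 81, a ratio of 0.75, inside the redistributed range. The main score includes fold enrichment, which was low for H3K27ac peaks under sox10 blocks (median 2.94). With domains scored by width alone the ratio was 0.73, with 55 peaks inside, in 19 clusters. That was slightly below the redistributed range of 58 to 84, which is too narrow for clustered peaks. The 5 domains with the most sox10 peaks were on chromosome 5 from 37592199 to 37635264 (6 peaks), chromosome 6 from 1367009 to 1388766 (6), chromosome 2 from 20754043 to 20764393 (4), the chromosome 6 domain starting at 43312484 (2) and chromosome 22 from 4956102 to 4995164 (2). In the superenhancer-like domains of the tumor, 6 sox10 peaks lay on H3K27ac peaks, against 5.33 ± 1.85 (SD) redistributed.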

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

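Of the tests in this part, those on the caller's threshold, on acetylated enhancers and on extra copies were chosen only after the result was seen. Blocks were likewise defined from these data, and the tests on enhancers and copies were split by block size after the values for all 122 blocks were known (5.04% of sox10 peaks in all blocks lay on cell line H3K27ac).

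Sox10 peaks overlapped cell line H3K27ac 3.51 times as often as shuffled peaks and tumor H3K27ac 0.24 times as often. The directions are opposite, and the difference itself was not tested. Without blocks the tumor value was 0.80, inside the shuffled range, and for isolated sox10 peaks it was 1.03. At a −log10 q of 10 or more the cell line value was 1.35, also inside the range. The sox10 list also had 6 peaks on the mitochondrial sequence, with fold enrichments from 1.81 to 2.47, while both H3K27ac lists had 0 there.

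Of explanations for the packing of sox10 peaks into blocks, peaks that barely passed the caller's threshold are argued against by the q-values. A −log10 q of 10 or more was found for 47.0% of sox10 peaks in blocks and 17.6% of the others, a difference of 29.4 percentage points (interval over clusters 23.3 to 36.9). Fold enrichment went the other way, with a median of 4.71 in blocks, 4.25 in blocks of 50 or more peaks and 5.27 outside blocks. Clusters of acetylated enhancers are argued against for the 16 largest blocks, where the share on cell line H3K27ac differed from that outside blocks by −13.4 percentage points (interval over blocks −16.5 to −10.3), and stay open for the 106 blocks of 5 to 49 peaks (−2.93, −7.99 to 2.60). In the 106 smaller blocks cell line H3K27ac peaks numbered 131, in 41 of the blocks and with 20 in the chromosome 10 block alone. The 100 kb flanks held 493, and tumor peaks numbered 3 inside against 516 (181, 23.3, 4.14 and 24.3 per Mb). Every block kept its full flanks, so flanks of neighbouring blocks overlap, can hold other blocks and can count a peak more than once. With 0.5 added to each count, the ratio of inside to flank was 39.3 times as large in the cell line (15.7 to 259, and 33.0 without the chromosome 10 block). Extra copies or raised background in both cell line libraries could raise this value, depending on the control used for calling, which is not given. The 65 blocks without a cell line H3K27ac peak cannot exclude this, since many blocks are short. The median span was 3.66 kb in blocks of 5 to 19 peaks. Acetylated enhancers specific to the line would raise the value too, so it cannot decide between them. Part of it also comes from the low tumor number inside blocks, which extra copies in the line would not cause. For the largest blocks this value was 2.34 (0.041 to 20.1) on 11 and 4 H3K27ac peaks inside, too few to decide, with all 11 in 1 block on chromosome 14 and a value of 0.10 without it, and DNA gained or carried in by the sox10 library alone was not tested.

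The second pattern is that cell line H3K27ac peaks under sox10 peaks were seldom found in the tumor. Their low fold enrichment and width are argued against as the whole cause: 6.93% of the 231 were found, against 43.3% to 54.6% of draws matched on deciles of fold enrichment and of width. Blocks alone are argued against too, since 17.8% of the 90 peaks outside blocks were found, against 43.3% to 63.3% in matched draws. A hypothesis left open is that these sites are specific to the line, either as bound enhancers or as sequence with extra copies. The cell line and the tumor also came from different fish and 1 of them was cultured, which was not tested.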

How the results depend on the processing

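The shuffles with clusters moved together and the settings for clusters, blocks and isolated sox10 peaks were chosen after seeing the data. Of 94 alternatives to 14 values, 10 left the lists as they were and say nothing about stability. Of the other 84, 69 kept their direction and their side of the shuffled range or, where nothing was shuffled, stayed within 1.5 times for a count and inside the 95% interval of the reported value for a share. For the sox10 overlaps, the shuffles for stricter q-values, other overlap rules, local moves and equal list lengths moved each peak alone. That shuffle called 44% of simulated clustered lists with no effect, so these calls are less certain. Some of the 69 still moved by over 1.5 times. At a −log10 q of at least 5, the share of sox10 peaks was 3.93% on cell line and 0.06% on tumor H3K27ac, and the ratio of superenhancer-like to other domains was 0.13. At 10 the tumor share and that ratio were 0, and with domains scored by width alone the ratio was 0.73. Ranked by −log10 q, sox10 lay on 0.44% of H3K27ac peaks in the highest decile, and with a stitching distance of 5000 bases 26.7% of the tumor domains were shared. The overlap of the H3K27ac lists, from both sides, and the sharing of superenhancer-like domains kept theirs in every alternative run. With both lists limited to a −log10 q of 10 or more, the share of sox10 peaks on cell line H3K27ac fell to 1.71% and inside the shuffled range. That cut kept 47.0% of sox10 peaks in blocks and 17.6% of the others. H3K27ac peaks under sox10 had a median −log10 q of 5.96 and an upper quartile of 10.1, so it removed most of them. The fall therefore cannot be read as a property of well-supported sox10 peaks, and its cause was not tested. At this cut the lists held 25544 cell line H3K27ac, 1759 sox10 and 28442 tumor H3K27ac peaks. With a stitching distance of 5000 bases the tumor had 1480 superenhancer-like domains. The share of H3K27ac peaks with a sox10 peak in the lowest decile was 1.36% and 0.43% at a −log10 q of at least 5 and 10, 1.13% when ranked by −log10 q and 0.46% without sox10 blocks, and that of the highest decile was 0% at both stricter q-values. Without sox10 blocks, 729 sox10 peaks were left. The share on tumor H3K27ac was then 1.37%, inside the shuffled range, and the ratio of superenhancer-like to other domains was 0.75, also inside. For isolated sox10 peaks the share on tumor H3K27ac was 1.76%, on the other side of the shuffled mean (8 peaks against 7.76) but within the shuffled range. The low overlap with the tumor was therefore not found once blocks were left out. With clusters as the unit, 128 of 687 (18.6%) touched cell line H3K27ac, above the shuffled range, and 15 (2.18%) touched tumor H3K27ac, below it. Neighbouring clusters were moved independently, so the ranges from moving clusters may also be too narrow. Promoter location, gene lists and the motif were not run, for lack of a Zv9 annotation and sequence. No paired analysis was possible because each group has 1 library. Unknown read depth limits every comparison of peak numbers.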

Other observations

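The tests in this part were set before their results were seen but after the peak numbers per chromosome were known.

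Peaks of the 2 H3K27ac lists were spread differently over chromosomes. Chromosome 4 held 2.73% of cell line peaks and 4.18% of tumor peaks (log2 ratio −0.62), and chromosome 11 held 2.63% and 3.48% (−0.41). The difference on chromosome 4 was not uniform: the first 25 Mb held 1041 cell line and 2237 tumor peaks, and the rest held 332 and 263. As log2 ratios of the shares of each list, not of these counts, the values were −0.86 and 0.58. The boundary was chosen after seeing the counts. Chromosome 9 held 4.78% and 3.74% (0.35), chromosome 10 held 4.03% and 3.21% (0.33), and chromosome 2 held 4.47% and 3.68% (0.28). Sox10 peaks were most numerous on chromosomes 12 (425 peaks) and 24 (420 peaks) and fewest of the assembled chromosomes on chromosome 1 (32 peaks).

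A few dense regions are argued against as the whole cause of the chromosome differences, because leaving out the 69 windows of 1 Mb that differed most kept 0.715 of the SD over chromosomes (0.155 against 0.216). A test of copies or read depth per chromosome, from the ratio of −log10 q at peaks shared by the lists, was also run and met its prediction. It was dropped, with its value, because it compares the caller's values between lists, which these files do not allow. Its outcome therefore counts neither for nor against copies or read depth. Chromosome copies, read depth and acetylation over long segments stay open as explanations.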
